A study of Gallus gallus with 6 samples.

How the data were processed

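RNA from pectoral muscle of female broiler chickens at 35 days of age was measured in 6 libraries, 3 from control birds and 3 from birds given 100 IU/kg of vitamin E. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads and fragmented, and the cDNA libraries were sequenced on an Illumina instrument. Sample titles and source names gave the group and the replicate number of each library. The kit's treatment of strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

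The values are FPKM per gene in each library, as deposited by the authors in 1 table of 20943 genes. The submitters' processing notes name TopHat2 2.0.12. The read counter, the annotation and the genome build are not given in the sources used here. Positions were taken from the deposited table, whose sequence records carry version 4. Chromosome names were given to 33 of these records by the chromosome on which a reference gene table lists the same gene symbols, with at least 94.4% of symbols on 1 chromosome for each record. 22 gene names in the table had been turned into dates by spreadsheet software and were kept out of the lists. Genes were matched to the lists by the name in the table only.

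FPKM values of a gene are whole multiples of what 1 read is worth in that library. Whole read numbers, gene lengths and library totals were recovered from these multiples for all 11320 tested genes, and the implied gene length was whole within a tolerance of 0.05 for 99.1% of them. On simulated values 98.3% of 11346 genes were recovered exactly. Reads were taken as the smallest whole numbers that fit the ratios of a gene's values. A gene whose read numbers share a common factor therefore gets too few reads and too short a length. The totals ranged from 14161399 to 25477341 reads, the highest in control replicate 1, and the recovered gene reads came to between 98.1% and 98.4% of them. Sampling error of reads is therefore smallest in that library. Within each group every pair of libraries differed by more than sampling noise, with a chi-square between 21.3 and 110 per degree of freedom. This sets the libraries against counting error only, and it does not show whether 2 libraries came from the same bird.

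Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, for genes with a mean of at least 1 FPKM over the 6 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment over all 11320 genes and a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, because there are 10 splits of the libraries, so none was used for single genes. The median log2 difference of all tested genes was 0.019, and none of the scalings moved it by more than 0.1.

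Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 25 of 26 lists that had at least 5 tested members. Camera compares the genes of a list with all other genes. The estimated correlation and fry, directional and mixed, were run as alternatives, and fry compares a list with no other genes. For each list, members were also adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol and groups that do not overlap, with open places filled by the smallest unadjusted p in each direction. It also named the 4 members with the smallest p in each called list, up to 2 in each other list, and 8 intramuscular fat genes. Other members of the lists are named where they passed over their list alone. Values of 3 genes that these rules name are not reported here, and the counts include them.

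The test was run on simulated reads drawn around the real means and library sizes with gene-wise dispersions, with 200 genes changed, over 11195 genes. It recovered 47% of genes changed by 2-fold and 78% of those changed by 4-fold, 6.72% of all its calls were false, and with no change simulated it made 0 calls. Genes were drawn independently and no library was made to stand apart, so these rates need not hold for the real libraries. Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum of 5 FPKM, TMM-type, median-of-ratios and quantile scaling, and limma without a trend, with a robust prior or with library quality weights. Blocks for the replicate number and for a digit in the sample description were fitted, and each library was left out in turn. Voom on the recovered reads and the removal of a trend on gene length were added after seeing the data. Figures were drawn with matplotlib 3.10.9.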

Results

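Pectoral muscle transcriptomes of female broiler chickens were compared at 35 days of age between control birds, which received 0 IU/kg of supplementary vitamin E, and birds given 100 IU/kg. The vitamin was supplied as DL-α-tocopheryl acetate, an ester of α-tocopherol, a lipid-soluble antioxidant of cell membranes. The series title places the comparison in a study of intramuscular fat. Each group had 3 poly(A)-selected libraries, and expression was given as FPKM (fragments per kilobase of gene, scaled by the size of the library) for 20943 genes. The labels describe 3 tissue samples per group and say nothing more about whether these came from separate birds, so the p-values measure the spread between these samples. The FPKM steps gave the reads behind each library. The controls had 25477341, 17203041 and 16239948 reads, and the vitamin E libraries had 14161399, 14838400 and 15288812 reads. A 1 kb transcript at 1 FPKM therefore rested on between 14.2 and 25.5 reads, fewer in each vitamin E library than in any control. Control replicate 1 stood apart on a first principal component that held 38.4% of the variance. It was at -34.4, where the other 5 libraries lay between -14.2 and 17.4. On that component all 3 vitamin E libraries, between 8.75 and 17.4, lay above all 3 controls, the highest at 5.87. Control replicate 3 was lowest on the second component (20.7% of the variance), at -26.4.

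In the birds given vitamin E, several transcripts for the use of fatty acids as fuel, for the breakdown of muscle protein and for collagen fibres stood above the control level, and clock genes differed in both directions. The fatty acid transporter gene CD36 averaged 13.6 ± 0.843 FPKM (SD, n = 3) in controls and 32.3 ± 2.38 FPKM with vitamin E. PDK4, whose kinase restrains the use of glucose by blocking pyruvate dehydrogenase, averaged 88.0 ± 31.2 and 376 ± 149 FPKM. TRIM63, which encodes the muscle ubiquitin ligase MuRF1, averaged 125 ± 33.2 and 403 ± 109 FPKM. The collagen gene COL3A1 averaged 635 ± 13.7 and 1111 ± 309 FPKM. In each of these 4 genes all 3 vitamin E libraries lay above all 3 controls, and each passed the test adjusted over the list alone, that is, within 1 of 26 gene lists fixed beforehand, but not over all genes. CD36, PDK4 and TRIM63 kept that call without each of the 6 libraries in turn. COL3A1 lost it without control replicate 1 or 3 or vitamin E replicate 1 or 2, and with no filter on low values.

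Over all 11320 genes with a mean of at least 1 FPKM, limma called 0 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.0656. At an unadjusted p under 0.05 there were 1031 genes, against 566 expected by chance, of which 676 were higher and 355 lower with vitamin E. The excess of higher genes was smaller after rescaling, at 560 higher and 477 lower with TMM-type scaling, 565 and 474 with median-of-ratios scaling and 592 and 445 with quantile normalization. Testing genes with a mean of at least 5 FPKM, or running voom on the recovered reads, each called CD36 and KCTD20, with adjusted p values of 0.0389 and 0.0460. The groups did not overlap in 1651 genes (14.6%, where chance gives 10%), and 1003 of these were higher with vitamin E. Genes vary together, so these chance figures do not tell how far a count can stray from them. Other splits of the 6 libraries into groups of 3 gave between 272 and 962 genes at an unadjusted p under 0.05. The share of genes without overlap was not computed for those splits. The unadjusted count of higher genes was 445 without control replicate 3 and 433 without vitamin E replicate 2, and that of lower genes was 617 without control replicate 2.

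**Figure D1:**
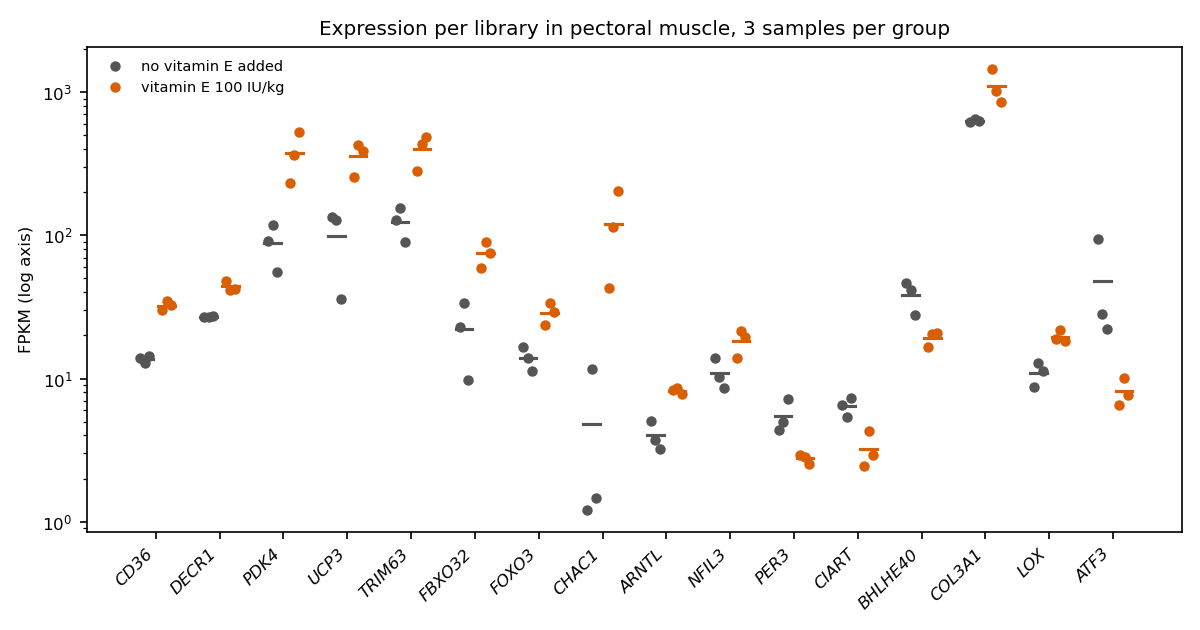
FPKM of 16 genes in each library on a log axis, with grey points for the control libraries, orange points for the vitamin E libraries and a bar at each group mean (3 libraries per group). CD36 lay between 12.7 and 14.4 FPKM in controls and between 29.9 and 34.6 FPKM with vitamin E, whereas the control values of ATF3 spread from 22.1 to 94.1 FPKM.

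Of the 10 genes with a symbol and the smallest p among those higher with vitamin E, none passed over all genes. KCTD20 (chromosome 26, 1533711 to 1552909), of the KCTD family of proteins with a tetramerization domain, averaged 21.6 ± 4.38 FPKM in controls and 72.8 ± 7.43 with vitamin E (SD, n = 3), a log2 difference of 1.72 ± 0.16 (SE). CD36 (chromosome 1, 11180362 to 11239813) differed by 1.18 ± 0.11. SLC43A2 (chromosome 19, 5303627 to 5332559), a transporter of large neutral amino acids, averaged 9.30 ± 4.52 and 48.5 ± 6.78 FPKM, a log2 difference of 2.38. The matrix and membrane genes SPON1, PDPN, COL4A5 and COL4A6 had log2 differences of 1.03, 1.26, 0.78 and 0.69, where the last pair encode chains of basement membrane collagen. LHFPL5, PAPSS2 and the transcriptional co-regulator CITED2 completed the 10, with differences of 1.02, 0.95 and 1.13. Positions are those of the deposited table, and the genome build is not given in the sources used here.

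The 10 corresponding genes with lower values did not pass over all genes either. The largest of their differences was that of DUSP10, a phosphatase of stress-activated MAP kinases, at 31.5 ± 8.32 FPKM in controls and 11.9 ± 2.83 with vitamin E (SD, n = 3; log2 difference -1.33 ± 0.23, SE). The endothelial lipase gene LIPG differed by -1.16 and the beta-lactamase-like gene LACTBL1 by -1.08. The kinase gene DYRK2, the focal adhesion gene LIMS1, the transcriptional repressor gene HES4, SCHIP1 and the tetraspanin gene TSPAN15 had differences of -0.82, -0.95, -0.75, -0.77 and -0.60. MIR7444 differed by -0.81, but its annotated length is 63 bases and reads of an overlapping transcript could not be separated from it. The histone H2A gene HIST1H2A4L4 differed by -0.81, and it is reported as uncertain because near-identical histone copies can share reads.

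Among genes of fatty acid uptake and oxidation, 4 of 30 tested members rose in the test adjusted over the list alone, against 0 over all genes. These were CD36 (adjusted p = 3.48e-04), DECR1, an auxiliary enzyme of the oxidation of unsaturated fatty acids (adjusted p = 0.00535), PDK4 (adjusted p = 0.00602) and the mitochondrial carrier gene UCP3 (adjusted p = 0.0318). PDK4 (chromosome 2, 23903132 to 23942823) differed by 2.07 ± 0.36 on the log2 scale, UCP3 by 2.02 ± 0.49 and DECR1 by 0.68 ± 0.11 (SE). UCP3 averaged 99.4 ± 55.0 FPKM in controls and 359 ± 89.8 FPKM with vitamin E (SD, n = 3), and it lost its call without any 1 of the 3 vitamin E libraries and with no filter on low values. CD36, DECR1 and PDK4 passed over the list alone without each of the 6 libraries in turn. As a group the list rose, with a median log2 difference of 0.16 (camera, adjusted p = 6.38e-04, and adjusted p = 0.388 with an estimated correlation). In fry's mixed test, which asks whether members change in either direction, its adjusted p was 5.62e-05. 

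Genes of muscle protein breakdown showed the same kind of change in a few of their members. Of 25 tested members, 4 rose in the test adjusted over the list alone and 0 over all genes. TRIM63 (chromosome 23, 3221781 to 3225453) differed by 1.68 ± 0.27 (SE; adjusted p = 0.00917). FOXO3, a transcription factor that drives ubiquitin ligase genes in muscle, differed by 1.00 ± 0.18 (adjusted p = 0.0107). FBXO32, which encodes the ubiquitin ligase atrogin-1, averaged 22.2 ± 11.9 FPKM in controls and 74.9 ± 15.8 FPKM with vitamin E (SD, n = 3; adjusted p = 0.0192). FBXO40 differed by 0.66 (adjusted p = 0.0207). TRIM63 and FOXO3 passed without each of the 6 libraries in turn, FBXO32 lost its call without vitamin E replicate 2 or 3, and FBXO40 lost its call without control replicate 1 or 3 or vitamin E replicate 1 or 2. The count over the list alone was 2 without vitamin E replicate 2. The list rose with a median of 0.20 (camera, adjusted p = 6.38e-04, and adjusted p = 0.388 with an estimated correlation).

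The circadian clock list held 3 risen and 3 fallen members among 16 tested in the test adjusted over the list alone, and 0 over all genes. The core activator gene ARNTL (chromosome 5, 7560351 to 7605130), which encodes BMAL1, averaged 4.00 ± 0.966 FPKM in controls and 8.21 ± 0.397 FPKM with vitamin E (SD, n = 3), and HLF, an output transcription factor, averaged 7.54 ± 1.75 and 15.7 ± 2.34 FPKM. Both had an adjusted p of 0.00795. NFIL3, a repressor of clock output genes, was the third risen member, with a log2 difference of 0.70 ± 0.22 (SE; adjusted p = 0.0376). The fallen members were PER3, BHLHE40 and CIART, all repressors in the clock, with log2 differences of -0.76, -0.94 and -0.82 and the same adjusted p of 0.00977. The call of NFIL3 was lost without control replicate 2 or 3 or vitamin E replicate 2 or 3, with no filter on low values and with either block (replicate number or description digit), and the other 5 passed without each library in turn. As members went both ways, camera gave no call for the list (adjusted p = 0.759), while fry's mixed test gave an adjusted p of 2.10e-04.

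Genes of the extracellular matrix and fibroblasts formed the list with the largest median difference, 0.49, and 33 of its 37 tested members were higher with vitamin E. Adjusted over the list alone 9 members rose, and over all genes 0. They were the fibrillar collagen genes COL1A2, COL3A1, COL5A1 and COL5A2, the collagen cross-linking enzyme gene LOX, the matrix proteoglycan and binding protein genes DCN, OGN and DPT, and PDGFRL. DCN averaged 393 ± 64.9 FPKM in controls and 570.2 ± 51.3 FPKM with vitamin E, and COL1A2 averaged 274 ± 44.0 and 417 ± 61.3 FPKM (SD, n = 3). The log2 differences of PDGFRL, LOX, COL5A2 and OGN were 0.89, 0.80, 0.56 and 0.76. The list rose with camera at an adjusted p of 8.16e-11, against an adjusted p = 0.388 with an estimated correlation. The count over the list alone depended on single libraries: it was 0 without control replicate 3, vitamin E replicate 1 or vitamin E replicate 2, and 2 without control replicate 1. It was 20 risen and 1 fallen without control replicate 2, and 19 risen and 2 fallen without vitamin E replicate 3. Of 14 other settings, the call of COL1A2 was lost with 5, those of COL5A1 and DCN with 4 each and that of COL3A1 with 1, and TMM-type, median-of-ratios and quantile scaling each lost COL1A2, COL5A1 and DCN. Control replicate 3 had the lowest mean of this list, at -0.38 relative to the mean of all libraries, and vitamin E replicate 1 the highest, at 0.37.

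**Figure D2:**
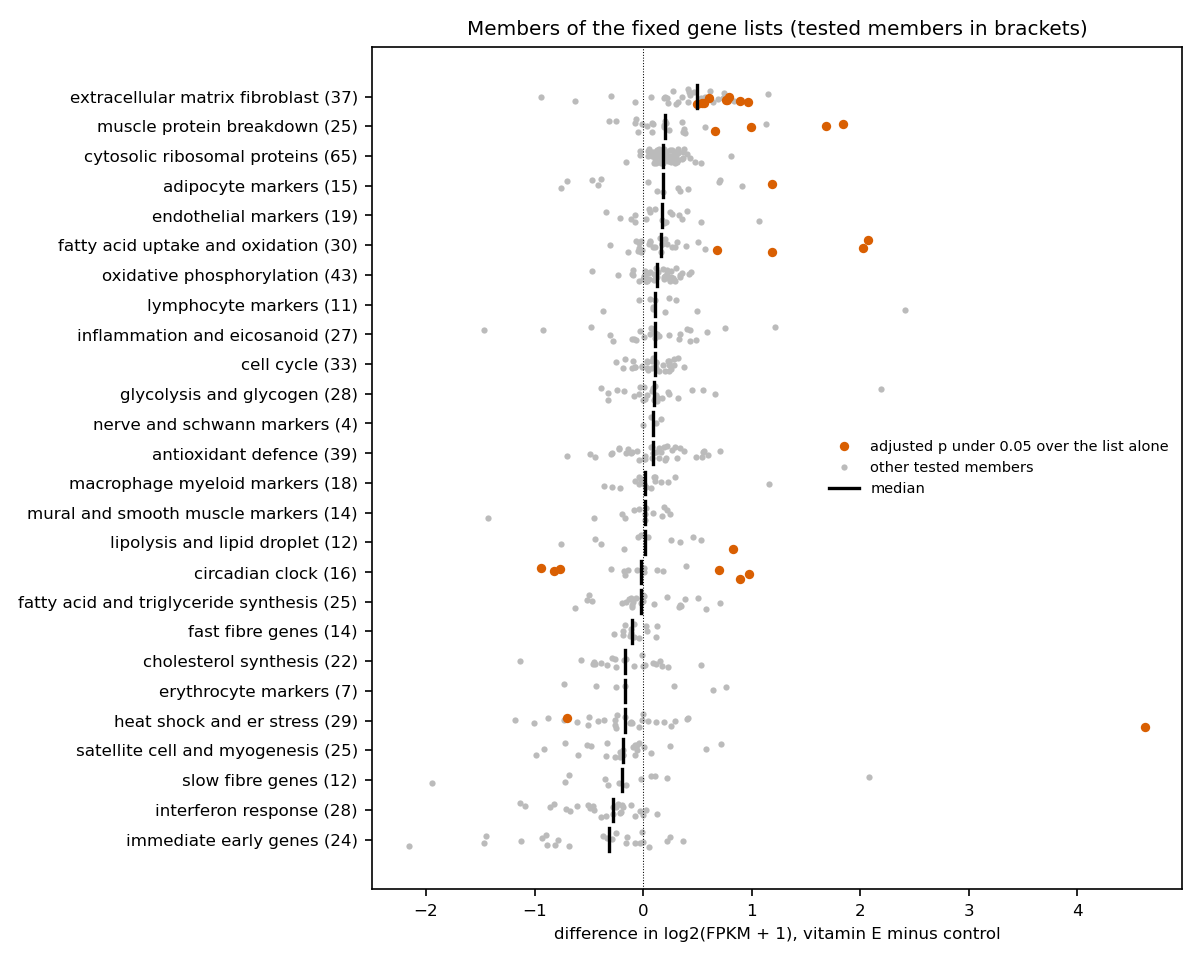
Difference in log2(FPKM + 1), vitamin E minus control, of each tested member of the 26 fixed lists, with 1 point per gene and a black bar at the list median. Orange points have an adjusted p under 0.05 over the list alone: 9 members of the matrix list lie to the right of 0, and clock genes lie on both sides.

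Among the genes of intramuscular fat, CD36 alone was called, in the test adjusted over the list alone (adipocyte markers, 1 of 15 members risen, adjusted p = 1.74e-04) and not over all genes. The other 7 of these genes passed neither test. The fatty acid binding protein gene FABP4 averaged 114 ± 47.4 FPKM in controls and 214 ± 84.2 FPKM with vitamin E (SD, n = 3), with overlapping groups and a log2 difference of 0.91. The lipoprotein lipase gene LPL differed by 0.32, the adipocyte regulator gene PPARG by 0.13 and the adipokine gene ADIPOQ by 0.18. Without single libraries LPL ranged from 0.18 to 0.43 and PPARG from 0.0074 to 0.20. The lipid droplet gene PLIN1 differed by 0.048 ± 0.38, and it turned to -0.023 with voom and -0.0036 with a pseudocount of 0.1. ADIPOQ turned to -0.0065 without control replicate 1, and PLIN1 turned to -0.27 without vitamin E replicate 2, -0.099 without vitamin E replicate 3 and -0.026 without control replicate 2. The fatty acid synthase gene FASN and the stearoyl-CoA desaturase gene SCD differed by -0.19 and -0.50. The adipocyte list had a median of 0.18 (camera, adjusted p = 0.149) and a mixed adjusted p of 2.35e-04. CD36 is also in the list of fatty acid uptake and oxidation, so the mixed results of these lists are not independent. What they would be without CD36 was not tested. The adipocyte list passed as higher with a minimum of 5 FPKM, where its mean was 0.40 against 0.15 (camera, adjusted p = 0.00310). Over the list alone 2 members rose without control replicate 2, and 1 rose and 2 fell without control replicate 3.

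In the list of fatty acid and triglyceride synthesis 0 of 25 members passed over the list alone or over all genes with limma, while 5 had an unadjusted p under 0.05, 2 higher and 3 lower. Its median was -0.023 and its mean 0.018, which turned to -0.018 with TMM-type scaling, -0.016 with median-of-ratios scaling, -0.0076 with quantile normalization and -0.028 without vitamin E replicate 1. Camera's direction was lower (adjusted p = 0.704), and the mixed adjusted p was 0.0279. SREBF1, the transcription factor of lipid synthesis genes, differed by -0.52 and LPIN2 by 0.33. The lipolysis and lipid droplet list gave no call (12 genes, median 0.014; camera, adjusted p = 0.397), with 1 member risen over the list alone and 0 over all genes, and its mean turned to -0.075 without control replicate 3 and -0.040 without vitamin E replicate 2. PLIN4 differed by 0.34 without passing. Cholesterol synthesis genes fell as a list, with a median of -0.17 (camera, adjusted p = 0.0352, and adjusted p = 0.691 with an estimated correlation). With limma 0 of its 22 members passed over the list alone, and 3 had an unadjusted p under 0.05, 1 higher and 2 lower. The sterol synthesis gene MSMO1, with the smallest p of the list, was higher by 0.53, against the direction of the list. INSIG1, a sterol sensor, differed by -1.14 and the sterol synthesis genes ACAT2 and SC5D by -0.46 and -0.33. INSIG1 ranged from -1.46 to -0.68 without single libraries. The call of the list was lost without control replicate 1 (adjusted p = 0.126), control replicate 3 (0.343) or vitamin E replicate 2 (0.571), and with 4 of the other settings, at adjusted p values between 0.0557 and 0.0591.

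Stress and immune transcripts were lower with vitamin E in 2 lists, each resting largely on 1 control library. Immediate early genes, which respond within minutes to stimulation or handling, fell as a list with a median of -0.31 (camera, adjusted p = 3.38e-04, and adjusted p = 0.691 with an estimated correlation). With limma 0 of 24 members passed over the list alone, and 6 had an unadjusted p under 0.05, all lower. Over the list alone 9 fell without control replicate 2, and 1 fell without control replicate 1 or 3. ATF3 averaged 48.2 ± 39.9 FPKM in controls and 8.14 ± 1.85 FPKM with vitamin E (SD, n = 3), and NR4A3, JUND and EGR1 differed by -1.46, -0.89 and -0.93. Control replicate 1 had a list mean of 0.93, where the other 5 libraries lay between -0.41 and -0.053, and without it the mean difference went from -0.50 to -0.17 and the call was lost (adjusted p = 0.0559). The interferon response list fell with a median of -0.28 (camera, adjusted p = 4.40e-04, and adjusted p = 0.691 with an estimated correlation), with 0 of 28 members past the test over the list alone and 2 at an unadjusted p under 0.05. Its transcription factor gene IRF1 differed by -0.82, and the class I antigen genes BF1 and BF2, which are near-identical and may share reads, by -0.71 and -0.61. Without control replicate 1 BF1 differed by -0.50 and BF2 by -0.28. Control replicate 2 alone had a list mean of 1.05, and without it the mean difference was 0.031 and the adjusted p 0.982.

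In the heat shock and endoplasmic reticulum stress list 1 member rose and 1 fell over the list alone among 29 tested, and 0 over all genes. CHAC1 (chromosome 5, 24438649 to 24440766), an enzyme that degrades the antioxidant glutathione, averaged 4.79 ± 6.0 FPKM in controls and 120.4 ± 80.3 FPKM with vitamin E (SD, n = 3), a log2 difference of 4.63 ± 0.78 (SE; adjusted p = 0.0147). The co-chaperone gene DNAJB1 differed by -0.70 (adjusted p = 0.0334). The call of CHAC1 was lost without control replicate 1 or 3, and that of DNAJB1 without control replicate 1 or 3 or vitamin E replicate 1 or 3, with no filter on low values, with either block and with voom. Without control replicate 2, 1 member rose and 10 fell. The list itself gave no call (median -0.17; camera, adjusted p = 0.0534), but passed as lower without control replicate 2 (8.24e-06) and with a gene length trend removed (0.0438), and its mean turned to 0.11 without control replicate 1, the library with the highest mean of the list, at 0.41.

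Antioxidant defence, the function most directly named by the treatment, held 39 tested genes, and 0 passed over the list alone or over all genes with limma. At an unadjusted p under 0.05 there were 4, all higher, and the median was 0.095 (camera, adjusted p = 0.192). The mean of the list was 0.091, and 0.036 without control replicate 3. Its members with the smallest p were the endoplasmic reticulum peroxidase genes GPX8 and GPX7, with log2 differences of 0.71 ± 0.20 and 0.56 ± 0.19 (SE). The list of inflammation and eicosanoids also gave no call (27 genes, median 0.11; camera, adjusted p = 0.501), and its mean turned to -0.026 without vitamin E replicate 2 and to -0.00049 without control replicate 3. With limma 0 of its members passed over the list alone and 5 had an unadjusted p under 0.05, among them the transcription factor gene CEBPD (1.22) and the chemokine gene CCL4 (-0.92).

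Cytosolic ribosomal protein genes rose as a list by a small amount, with 62 of 65 members higher and a median of 0.19 (camera, adjusted p = 3.81e-10, and adjusted p = 0.624 with an estimated correlation). With limma 0 of them passed over the list alone and 16 had an unadjusted p under 0.05. RPL3, RPS19 and RPL29 differed by 0.53, 0.48 and 0.41, values that processed pseudogenes with similar sequence can affect. Oxidative phosphorylation genes rose as a list with a median of 0.12 (camera, adjusted p = 0.0175, and adjusted p = 0.691 with an estimated correlation), and 0 of 43 passed over the list alone with limma, where 3 had an unadjusted p under 0.05. NDUFA1, COX7A2, COX4I1 and COX6C, subunits of respiratory complexes, differed by 0.44, 0.43, 0.34 and 0.30. The call of this list was lost without control replicate 1 (adjusted p = 0.768) or vitamin E replicate 1 (0.137), with library quality weights (0.107) and with a gene length trend removed (0.0787). Glycolysis and glycogen genes gave no call (28 genes, median 0.099; camera, adjusted p = 0.309). Within that list the glycolytic regulator gene PFKFB3 averaged 20.9 ± 16.5 FPKM in controls and 81.6 ± 21.3 FPKM with vitamin E (SD, n = 3), and the glycogen precursor enzyme gene UGP2 differed by 0.66, neither passing over the list alone.

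Genes of satellite cells and myogenesis fell as a list, with a median of -0.19 (camera, adjusted p = 0.0239, and adjusted p = 0.691 with an estimated correlation). With limma 0 of 25 passed over the list alone and 3 had an unadjusted p under 0.05. The growth factor gene IGF1 was higher by 0.72, against the direction of the list, while the myogenic factor gene MYOG, the satellite cell gene PAX7 and IGF2 differed by -0.60, -0.51 and -0.99. Control replicate 1 had a list mean of 0.49 and the other 5 libraries between -0.16 and -0.017. Without control replicate 1 the mean difference was 0.0015 and the adjusted p 0.621, and without vitamin E replicate 1 the adjusted p was 0.0768. It was 0.0591 with a minimum of 5 FPKM and 0.0704 with library quality weights.

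Fibre genes gave no call. The 14 fast fibre genes, which make up the bulk of breast muscle contractile transcripts, had a median of -0.098 (camera, adjusted p = 0.149), with TNNC2 at 6268 ± 474 FPKM in controls and 5503 ± 161 FPKM with vitamin E (SD, n = 3) and ACTN2 at a log2 difference of -0.27. The 12 slow fibre genes had a median of -0.19 (camera, adjusted p = 0.149). The mean of the slow fibre list turned to 0.033 without control replicate 1, and the list passed as lower without vitamin E replicate 1 (adjusted p = 0.0432). Its members with the smallest p went apart in single libraries: MYBPC1 was at 180.5 FPKM in control replicate 1 and at most 27.3 FPKM elsewhere, and FHL2 was at 88.7 FPKM in vitamin E replicate 1 and 9.91 FPKM in vitamin E replicate 3. Cell cycle genes gave no call (33 genes, median 0.11; camera, adjusted p = 0.187), with CCNB2 and NCAPG at 0.32 and 0.38. That list passed as higher without control replicate 3 (0.0191) or vitamin E replicate 1 (8.83e-05), and its mean turned to -0.012 without vitamin E replicate 3.

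Markers of the other cell types of muscle gave no call with camera, and 0 members passed over their list alone with limma. Endothelial markers had a median of 0.18 (19 genes, adjusted p = 0.0558), with 3 members at an unadjusted p under 0.05, and ENG and CLDN5 at 0.41 and 0.53. They passed as higher without control replicate 2 (0.00654) or vitamin E replicate 3 (0.0293), with a minimum of 5 FPKM (0.00917) and with the replicate number as a block (0.0456). Lymphocyte markers had a median of 0.11 (11 genes, adjusted p = 0.149), with 1 member at an unadjusted p under 0.05, and passed as higher without control replicate 2 (0.0174) or vitamin E replicate 1 (0.0281). The immunoglobulin joining chain gene IGJ averaged 13.9 ± 12.9 FPKM in controls and 71.7 ± 40.3 FPKM with vitamin E (SD, n = 3), with overlapping groups, and the T cell gene CD3D differed by 0.50. Macrophage and myeloid markers had a median of 0.019 (18 genes, adjusted p = 0.832), with LY86 at 1.16, the 1 member at an unadjusted p under 0.05, and LAPTM5 at 0.23, which turned to -0.074 without control replicate 3. That list passed as higher without control replicate 2 (0.0377) and as lower without control replicate 3 (0.00137), and its mean turned to -0.033 without vitamin E replicate 2.

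Mural and smooth muscle markers had a median of 0.017 and a mean of -0.098, and camera's direction was lower (14 genes, adjusted p = 0.473). SYNPO2 differed by -0.45, the 1 member at an unadjusted p under 0.05, and CNN1 was at 141 FPKM in control replicate 1 and at most 22.0 FPKM elsewhere. The mean of the list turned to 0.014 without control replicate 1 and 0.0055 without vitamin E replicate 3. Erythrocyte markers had a median of -0.17 and a mean of 0.016, which turned to -0.022 with TMM-type scaling, -0.020 with median-of-ratios scaling and -0.0051 with quantile normalization, and camera's direction was lower (7 genes, adjusted p = 0.854). The globin genes HBAA and HBAD, which share sequence, differed by 0.64 and 0.76 and were its 2 members at an unadjusted p under 0.05. Of the nerve and Schwann cell markers 4 reached 1 FPKM, too few for a list test, with 0 at an unadjusted p under 0.05. MBP differed by 0.073 and L1CAM by 0.17, and both signs turned when single libraries were left out, to -0.098 for MBP without control replicate 2 and -0.25 for L1CAM without vitamin E replicate 2.

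**Figure D3:**
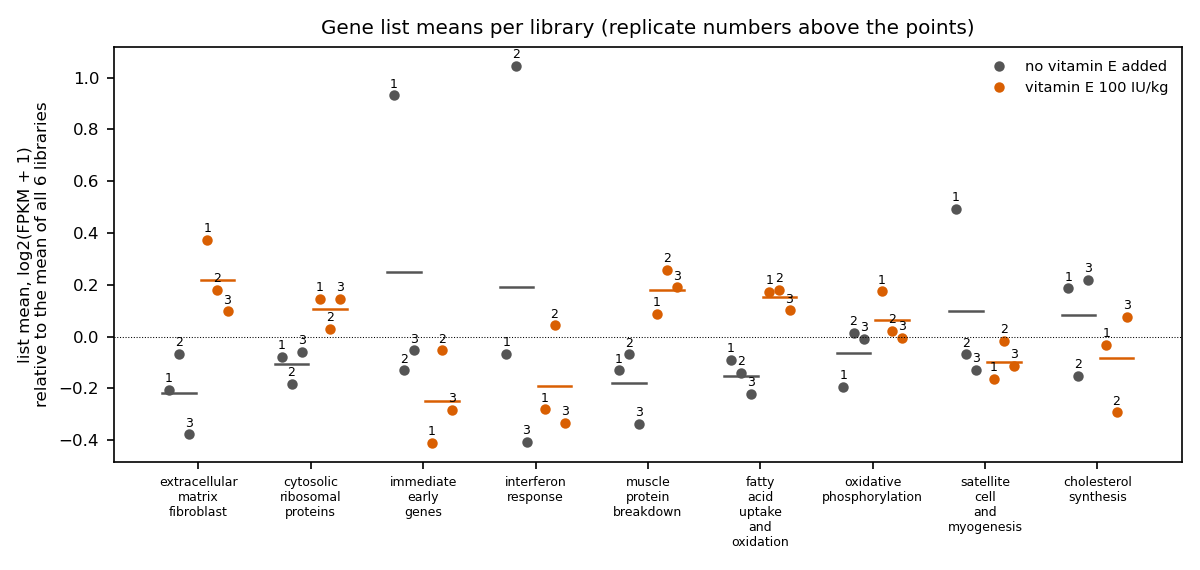
Mean log2(FPKM + 1) of the 9 lists past camera's threshold in each library, relative to the mean of all 6 libraries, with replicate numbers above the points and a bar at each group mean. Control replicate 1 stands at 0.93 in immediate early genes and control replicate 2 at 1.05 in interferon genes, while for fatty acid uptake and oxidation the controls lie between -0.22 and -0.091 and the vitamin E libraries between 0.10 and 0.18.

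Across the fixed lists, 26 of 613 tested genes passed in the test adjusted over the list alone, 22 higher and 4 lower with vitamin E, and 0 passed over all genes. The total of 26 rested on single libraries, as it was 12 without vitamin E replicate 2 and 64 without control replicate 2, and between 16 and 35 without any other library. In other lists with no member past the test over the list alone, leaving out 1 library let 3 glycolysis and glycogen genes rise (without control replicate 2), and 1 member pass in each of the antioxidant, cholesterol, inflammation, interferon, lymphocyte, macrophage and slow fibre lists. Camera called 9 of 25 tested lists with its preset correlation, 5 higher and 4 lower, and 0 with an estimated correlation or with fry's directional test. Other ways of splitting the 6 libraries into groups of 3 gave between 5 and 11 lists with camera. Fry's mixed test called 7 lists in the comparison of the groups and at most 1 in the other splits.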

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

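Of the tests in this part, voom on the recovered reads and the removal of a gene length trend were chosen only after the data were seen. Against the alternatives, the named genes kept their direction and their side of the threshold in 1841 comparisons. They gained a call in 4 and changed sign in 11. As limma called 0 genes over all genes, no named gene had a call to lose. The 1841 comparisons therefore show mostly that uncalled genes stayed uncalled with the same sign. The lists kept their direction and their side of the threshold in 470 comparisons. They lost a call in 33, gained one in 13 and changed sign in 33.

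Limma called 2 higher genes with a minimum of 5 FPKM and 2 with voom, against 0, and 1031 genes had an unadjusted p under 0.05. The unadjusted counts were 443 higher and 236 lower with the 5 FPKM minimum, which tests fewer genes, and 549 lower with no filter. Leaving out single libraries gave 433 to 940 higher genes against 676 and 257 to 617 lower genes against 355. Lists called higher numbered 4 to 8 against 5 without single libraries, and lists called lower 1 to 4 against 4. With the 5 FPKM minimum 2 lists were called lower. With an estimated correlation 0 were called higher and 0 lower, and fry's directional test gave 0 and 0. The cause was not tested. The other alternatives left these counts within 1.5 times.

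Mean log2 differences that changed sign belonged to lists and genes with no call, except for interferon and satellite cell genes. The clock list was at -0.0038, and at 0.013 with no filter, 0.20 with the 5 FPKM minimum, 0.020 with quality weights and 0.00048 with the length trend removed. The erythrocyte list was at -0.0013 with the 5 FPKM minimum, -0.022 with TMM-type, -0.020 with median-of-ratios and -0.0051 with quantile scaling. The fatty acid and triglyceride synthesis list was at -0.018, -0.016 and -0.0076 with these 3 scalings. PLIN1 was at -0.0036 with a pseudocount of 0.1 and -0.023 with voom. The cause was not tested for these either.

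Leaving out each library in turn gave these ranges of mean log2 difference: cell cycle -0.012 to 0.21, clock -0.054 to 0.047, erythrocyte -0.094 to 0.15, fatty acid synthesis -0.028 to 0.066, heat shock -0.25 to 0.11, inflammation -0.026 to 0.15, interferon -0.68 to 0.031, lipolysis -0.075 to 0.21, macrophage -0.25 to 0.27, mural -0.20 to 0.014, satellite cell -0.31 to 0.0015 and slow fibre -0.33 to 0.033. The genes LAPTM5, L1CAM, MBP, ADIPOQ and PLIN1 ranged from -0.074 to 0.39, -0.25 to 0.40, -0.098 to 0.31, -0.0065 to 0.38 and -0.27 to 0.52.

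The labels do not say that replicate numbers pair the samples. Deviations of samples with the same number correlated at -0.13, 0.15 and 0.012, and only for replicate 2 did each sample correlate best with its own number. With 3 samples per group this cannot exclude a pairing. With the replicate number as a block, limma called 0 higher and 0 lower genes (lowest adjusted p 0.248, against 0.0656), and 1 further list passed, endothelial markers at 0.0456. A block on a digit in the sample description also gave 0 genes (lowest adjusted p 0.107). Depth limits low genes most, since 1 FPKM over 1 kb is 14.2 reads in the shallowest library.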

Other observations

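Leaving out single libraries was planned, and the other tests in this part were chosen after the data were seen. What was expected of gene length and of the second list, of fasting and glucocorticoid-responsive genes, was written before the results of those tests. So was what was expected of the number of called lists and of the number of clock genes. The genes named in the next 2 paragraphs were chosen after their values were seen, except for the members of that second list.

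Of single genes outside the lists, 3 are given here that had higher values with vitamin E and did not pass over all genes. SESN1, a brake on growth signalling by mTORC1, averaged 72.1 ± 38.3 FPKM in controls and 291 ± 25.6 with vitamin E (SD, n = 3). ASB2, a ubiquitin ligase subunit of muscle, averaged 23.4 ± 16.5 and 90.6 ± 18.5 FPKM, and ZBTB16, a glucocorticoid-responsive transcription factor gene, averaged 3.18 ± 1.07 and 8.52 ± 0.843 FPKM. In a second list of 13 tested fasting and glucocorticoid-responsive genes, written before its values were looked at, 5 rose in the test adjusted over the list alone and 0 over all genes with limma. They were TSC22D3, KLF9, FKBP5, DDIT4 and GLUL, with log2 differences of 1.00, 0.69, 1.56, 1.37 and 1.88. Each was higher in 3 of 3 vitamin E libraries than in any control. The other members did not pass and went both ways. SESN3, TXNIP, PIK3R1 and INSR differed by 0.30, 0.62, 0.18 and 0.089. ERRFI1, CDKN1A, BCL6 and EIF4EBP1 differed by -0.65, -0.52, -0.034 and -0.025. Of 786 gene ontology terms tested with camera, 3 passed, all higher: extracellular matrix organization, collagen fibril organization and protein peptidyl-prolyl isomerization, each with an adjusted p of 0.0487. Their camera p values with an estimated correlation were 0.189, 0.112 and 0.0237. These are not adjusted over the 786 terms, so none of them stands as a call.

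Transcripts of 2 immunoglobulin genes were high in 2 of the 3 vitamin E libraries. IGLL1, a light chain gene, was at 46.0, 333 and 328 FPKM in vitamin E replicates 1 to 3 and at most 69.4 FPKM in controls, and VH26L1 was at 22.3, 103 and 96.1 FPKM against at most 15.1 FPKM. Copies of such genes share reads, so single values are uncertain. Single genes were also high in control replicate 1, and they were picked for that. The myosin heavy chain gene MYH1A was at 962 FPKM there and at most 168 FPKM in the other 5 libraries, XIRP1 at 191 against at most 40.7, KLHL40 at 161 against at most 34.1 and HSP25 at 478 against at most 201.

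The first pattern is the joint difference of fuel, protein breakdown and clock genes. The fuel and protein breakdown part did not rest on control replicate 1, since the mean log2 difference of all 55 tested members of these 2 lists without that library was 1.08 times that with it. A longer time since feeding, or stress hormones, in the vitamin E birds may account for part of it, and the second list cannot tell them apart. That list of fasting and glucocorticoid-responsive genes had a median log2 difference of 0.30. Its camera p was 0.000361, and 0.0373 with an estimated correlation. Ontology terms went both ways and did not pass. Cellular response to starvation (camera, unadjusted p = 0.00527) and ubiquitin-dependent protein catabolic process (0.0102) were lower, and fatty acid beta-oxidation (0.00869) was higher. A difference in the hour of sampling stays open. In the first assignment, with 4 genes left unplaced, activator and repressor arms of the clock differed in median by 0.87, above the bound of 0.5. With all 16 genes placed, an assignment made after values were seen, they differed by 0.29, below that bound. The bound itself was also written after the data were seen. Both values count NFIL3, a repressor, in the activator arm, and with it in the repressor arm they were 0.68 and 0.22. Both also count TEF in the repressor arm. The value with all genes placed further counts HLF there, an output transcription factor with a log2 difference of 0.98. Other places for TEF and HLF were not tried. The sources used here give neither the hour of sampling nor the time since feeding, and an effect of the diet itself remains among the open explanations, as untested.

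The second pattern is the rise of matrix genes. Gene length bias is argued against, because the list mean with a length trend removed was 1.01 times the mean before. A lower share of fibre RNA as the whole cause stays open. The matrix list exceeded the mean of endothelial, mural, macrophage and lymphocyte lists by 0.32, which is 2.77 standard errors over libraries. That passed a bound set after the data were seen, but 3 libraries per group are too few to decide. In vitamin E replicate 1 the matrix list was at 0.37 and these lists at most at 0.11. In vitamin E replicate 2 it was at 0.18 and they were at 0.18, 0.059, 0.22 and 0.25. In vitamin E replicate 3 it was at 0.097 and they were at -0.035, -0.26, -0.10 and 0.29. The fast fibre list was at 0.059, 0.063 and -0.0095 in control replicates 1 to 3. It was at -0.062, -0.054 and 0.0037 in vitamin E replicates 1 to 3, so the groups overlapped. Sampling of more connective tissue in some pieces of muscle was not tested and may contribute, and an effect of the diet remains open.

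The third pattern is the fall of immediate early genes. A high level in control replicate 1 alone is consistent with most of it, since the mean difference without that library was 0.337 times that with it. Whether that bird was handled differently or its sample held other tissue was not tested. The remainder did not pass, at an adjusted p of 0.0559.

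The 6 libraries can be split in 10 ways, which is too few for a share under 0.05. The real grouping gave 1031 genes at an unadjusted p under 0.05 and the highest other split 962, so that 1 split in 10 gave as many genes. At an adjusted p under 0.05 the real grouping gave 0 genes, while 2 of the other splits gave 1 gene each. The real grouping gave 26 genes past the threshold over their list alone (12 to 64 without single libraries) against 10 at most, in 1 split, and 6 clock genes against 0, in 1 split. It gave 7 lists past the mixed test against 1 at most, again in 1 split. For lists past camera's threshold the real grouping gave 9 and the highest other split 11, and 5 of the 10 splits gave at least 9.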
